A study of Glycine max with 23 samples.

How the data were processed

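Small RNA was sequenced from 23 tissue libraries of soybean (Glycine max cv. Williams 82), without replicates of any tissue. Per the labels' protocols, total RNA was extracted with TRIzol, size-selected on a gel, made into small RNA libraries and sequenced on an Illumina instrument. The series title names microRNA gene evolution in the paleopolyploid soybean genome, a genome that carries traces of ancient duplications. Reads were not processed again.

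One table of 3933 entries was used, each a mature sequence placed on a hairpin, with coordinates for all but 29 entries. Its values are a normalised signal that the authors scaled to tags per 5000000 sequenced tags (TP5M), per the file headers. BWA is named in the submitters' processing notes without its role or version. The mapping settings, the genome build and the rule that assigned reads to entries are not given in the sources used here, so coordinates are printed as the table gives them. Reads from near-identical copies of a miRNA gene cannot be assigned to one copy, so entries with the same mature sequence were treated as 1 item, which left 2839 distinct sequences. Of these, 580 stood in more than 1 entry, and the entries of 2 disagreed in value, with at most 1 value above 0 per library, which was kept. 413 sequences carried a miRNA name, 83 an older name and 2343 only a locus number of the form M0766-3p. Locus numbers are given here with a family where the sequence shares 18 nt in a row with a named one. Failing that, the family is that of a named hairpin which its own hairpin overlaps on the same strand. Neither link says anything of its targets. The known functions mentioned are those of a family's main product, and the opposite arm of a hairpin need not share them.

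Libraries were matched to the table's columns by the number in each sample's title. The labels also hold another number in brackets, which would give a different match. As a check only, the mean correlation of log2 values was 0.833 within and 0.728 between organs with the title number, against 0.762 and 0.739 with the bracket number. The pattern of 1 sequence over the columns had been seen before the match was written down, and the match rests on the titles.

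The step between the low values of a library gave the worth of 1 read, from 0.742 to 1.38 TP5M. All 41139 values of up to 200 reads were whole numbers of reads within 0.1 (100.0%). Library totals, computed from that step, ran, in units of 1e6 tags, from 3.63 in the leaf bud to 6.74 in the germination cotyledon. The limit that 0 reads allow, taken as 3 reads, ran from 2.22 to 4.14 TP5M. Intervals and these limits cover counting error only, since PCR copies of one molecule cannot be told apart.

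Libraries were grouped into 8 organs from the labels: 6 leaf, 5 flower, 3 pod, 3 seed, 2 stem, 2 cotyledon, 1 root and 1 leaf bud. Libraries of an organ come from different ages or stages, so SDs and p-values set a difference between organs against the spread between stages, not against biological replicates. For each of the 595 sequences with a mean of at least 5 TP5M, log2(TP5M + 5) was fitted in limma 3.58.1 with a mean per organ over all 23 libraries, eBayes with trend and Benjamini-Hochberg adjustment at 0.05. Log2 differences are on that scale, which understates changes of low sequences. Folds are ratios of mean TP5M. Where a group was at 0 throughout, the fold is a lower bound against the largest 3 read value of single libraries in the 2 organs. The planned edgeR test with DESeq2 beside it was meant for raw counts and was not run in that form, since the values are scaled. An edgeR 4.0.16 quasi-likelihood test on the recovered reads was added instead. On simulated values with 200 of the 595 sequences changed, limma found 43.3% of 4-fold changes for flower against leaf, 35.8% for pod against flower, 7.5% for seed against pod and 23.9% for seed against leaf. False calls made up 1.3%, 6.8%, 0% and 1.9% of its calls.

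The 10 family lists, the tests, the named sequences and the alternatives other than those said to be added were chosen before the data were examined. The lists are families shared by most flowering plants (ancient), legume families, phase change, auxin, meristem and organ shape, copper, nutrient, regulators of defence genes, small RNA machinery, and families reported in phloem sap as a list for vascular content. They were tested with camera at a preset correlation and camera with an estimated correlation. fry was run for a shift one way and, in a mixed form, for changes in either direction. Each test was adjusted over 40 list results. Named sequences are, for each contrast, the called member with the largest difference of each family or unnamed locus, up to 10 higher and 10 lower; the 10 most abundant sequences; the 3 most abundant members of each list; and for pairs of single libraries up to 5 families on each side that differ by 4-fold or more. Other list members named as examples were chosen after their values were seen. Numbers of sequences detected and length shares were compared with exact two-sided permutation tests, and family breadth with a two-sided permutation test of 100000 resamples.

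Alternatives changed the pseudocount, the filter, the scaling (TMM, which sets the libraries' typical sequences level), the treatment of repeated entries, the eBayes trend, the libraries fitted, and left out each library in turn. Added after seeing the data were the edgeR test, young or later leaf only, families widened by related sequences and thinned reads. Also added were a term for 6 libraries with extra sequences found in no library outside them, and fits that left some sequences out. Those left out were at 0 in some libraries and at 20 TP5M or more in all others. A wider form of that rule, at 10 TP5M, was added after results at 20 had been seen. R 4.3.3, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used. Predicted targets, hairpin structure and gene duplicates were not analysed here.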

Results

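The 23 libraries covered soybean development from germination to senescence. Leaf was sampled as new leaf at germination, new and old leaf at the trefoil stage and at flower bud differentiation, and senescent leaf. Flowers were sampled as flower bud, bud before flowering, florescence on 2 dates, and 5 days after flowering. Pods came from weeks 1, 2 and 3 and seeds from weeks 6, 8 and 10. Stem and cotyledon were each taken at germination and trefoil, root at germination, and the leaf bud at flower bud differentiation. The sequences in the table took 2.04% of the tags in root (95% interval 2.03 to 2.06) and from 4.61% in germination leaf to 17.5% in old cotyledon elsewhere.

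miR159a-3p, which targets GAMYB-like transcription factors, was the most abundant sequence of every library, with a mean of 167591 TP5M and 19.2% to 42.9% of the summed signal of a library (chromosome 7, 9524917 to 9525127, minus strand). miR166a-3p, which targets HD-ZIP III genes, averaged 34389 TP5M and miR168a, which targets AGO1, 23313. Next came miR1507a, a legume regulator of NLR defence genes (16970), miR396b-5p, which targets growth-regulating factors (13855), M4031-5p of the miR167 family (12969), miR2118a-5p (12785), gso-miR3522a (11049), M4779-5p, related to miR1507 (10143), and miR1509a (8747). Ancient families were also found most widely. The 23 ancient families reached 5 TP5M in 22.5 ± 1.56 libraries (SD over families) and 20 of them in all 23, whereas the 171 other named families did so in 8.15 ± 9.36 libraries, 25 in all 23 and 67 in none (permutation p = 1e-05, the smallest that the resamples can give). Families are not independent replicates. The limit applies to the sum of a family's sequences, so families with more sequences pass it more easily. Ancient families held 133 of the 236 named sequences tested, and family size was not accounted for.

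The level of 235 of 595 sequences (39.5%) differed among leaf, flower, pod and seed in limma's moderated F-test, and 300 had an unadjusted p under 0.05. The median log2 difference of all sequences was 0.435 for flower minus leaf, −0.171 for pod minus flower, −0.639 for seed minus pod and −0.377 for seed minus leaf. With TMM scaling these medians were 0, −0.006, −0.155 and −0.2, so each direction holds relative to the tag total of a library. The medians also moved with other settings: flower minus leaf was 0.062 without a filter and −0.39 with edgeR and TMM, and seed minus leaf −0.012 without a filter and −1.147 with edgeR. With a term for 6 libraries that hold extra sequences found in no library outside them, pod minus flower was −0.681 and seed minus pod −0.12.

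**Figure D1:**
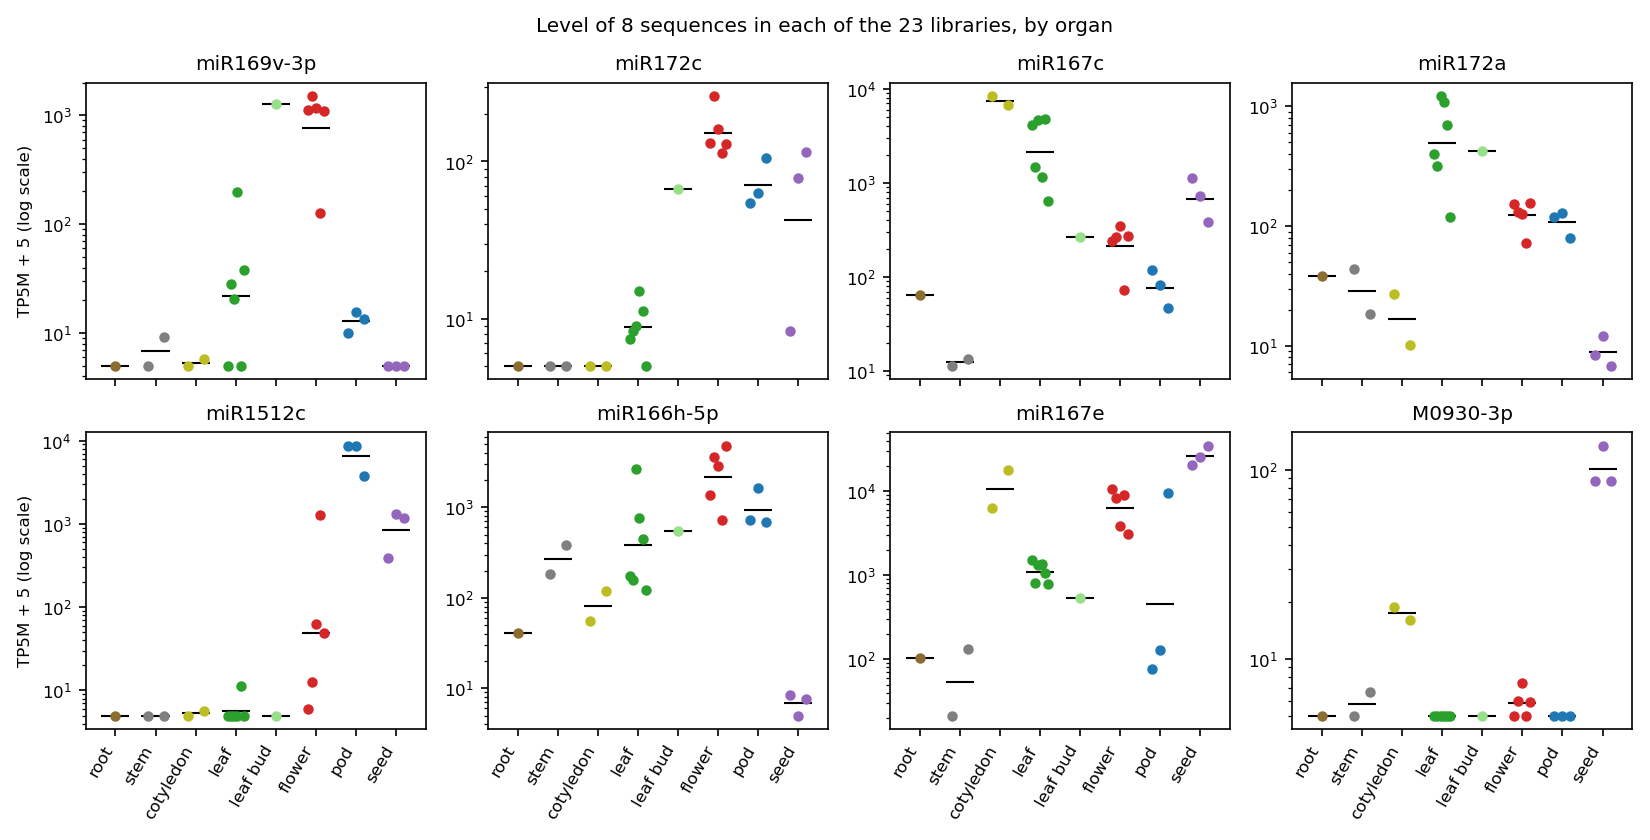
Level of 8 sequences in each of the 23 libraries (vertical axis, TP5M + 5 on a log scale) by organ (horizontal axis); points are libraries and lines are means of log2(TP5M + 5). miR172a averaged 635 TP5M in leaf and 4.09 in seed, and miR1512c 7003 in pod and 1.03 in leaf.

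Flower against leaf compares reproductive with vegetative organs. miR172, which represses AP2-like genes in flowering and floral patterning, was split by member. miR172c was 154 ± 59.6 TP5M in flower (SD, n = 5) and 4.31 ± 3.47 in leaf (n = 6), a 35.8-fold difference (log2 4.11 ± 0.51 SE, adjusted p = 0.0001), whereas miR172a was lower in flower (123 ± 33.7 against 635 ± 442, log2 −1.99, adjusted p = 0.0132), as was miR172b-5p (43.4 ± 27.1 against 358 ± 205, log2 −2.86). miR167, which targets the auxin response factors ARF6 and ARF8, was split too. miR167c fell from 2802 ± 1910 in leaf to 234 ± 100.7 in flower (log2 −3.34 ± 0.59, adjusted p = 0.000721), and miR167e rose from 1139 ± 312 to 6967 ± 3273 (log2 2.50, adjusted p = 0.0472). miR164a-3p, the opposite arm of a miR164 that targets NAC genes of organ boundaries, was 237 ± 109 in flower and 34.2 ± 60.2 in leaf.

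The largest rise in flower was that of miR169v-3p, from a family that targets NF-YA factors (999 ± 518 against 44.1 ± 74.0 TP5M, log2 5.14 ± 0.79, adjusted p = 0.000375). It was followed by miR4392 (1053 ± 1489 against 8.06 ± 9.42, log2 4.78) and M1130-3p of miR164 (log2 4.37). M6352-3p of miR394, a family that targets LCR, was 1004 ± 361 against 105 ± 152 (log2 4.20). Further rises were those of M4341-5p of miR172 (log2 4.12), M4051-3p of miR319, which targets TCP genes (6186 ± 3425 against 526 ± 380, log2 3.94), M1574-3p of miR394 (log2 3.74) and miR828a, which targets MYB genes (133 ± 116 against 3.64 ± 2.52, log2 3.35). Lower in flower than in leaf were M6343-3p of miR156 (0.57 ± 1.27 against 490 ± 727), M5469-3p (log2 −4.22) and M5469-5p (log2 −2.96) of 1 hairpin without a family. M1578-3p of miR156 (log2 −3.07) was also lower, as were gso-miR3522a (695 ± 273 against 10810 ± 13844, log2 −2.76), miR169n (log2 −2.34), M4097-5p of miR172 (log2 −2.27) and M5497-3p of miR169 (log2 −2.01). In all, 126 sequences were higher and 22 lower (61 and 38 with TMM scaling). 228 had an unadjusted p under 0.05, and 59 did not overlap between the organs, where chance gives 0.433%.

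By list, 11 of 45 meristem and organ shape members rose and none fell (11 and 0 adjusted over the list alone; 7 and 1 with TMM), among them miR319a (14293 against 2360 TP5M) and miR171m (3600 against 854). Of all 595 sequences 126 rose and 22 fell. Neither camera nor fry for a shift one way called the meristem list (adjusted p = 0.241 and 0.0554), but mixed fry did (adjusted p = 0.000749). Of 16 phase change members 1 rose and 6 fell (1 and 7 adjusted over the list alone), with a median log2 of −1.06 and a camera call (adjusted p = 0.000628; adjusted p = 0.416 with an estimated correlation). The 13 copper members, from families that target laccases, superoxide dismutases and plantacyanins, had a median of −1.45 and a camera call (adjusted p = 0.000225; adjusted p = 0.887 with an estimated correlation), yet limma called none of them (0 adjusted over the list alone). 6 copper members had an unadjusted p under 0.05, TMM gave 3 lower, and edgeR called 7, or 11 with TMM. Among copper members miR398c was 338 ± 164 against 5008 ± 6622 and miR408a-3p 77.9 ± 22.7 against 701 ± 1189. Of 12 auxin members 4 rose and 2 fell (6 and 2 adjusted over the list alone; 2 and 2 with TMM), and of 133 ancient members 23 rose and 9 fell (23 and 9; 14 and 15 with TMM). Of 68 legume members 7 rose (5; 3 and 1 lower with TMM), and of 40 nutrient members 3 rose and 1 fell (1 and 0; 1 and 1 with TMM). Of 26 phloem sap members 1 rose (0; with TMM 3 fell and none rose). edgeR called 5 meristem members in place of 11 (5 with TMM), 4 auxin members in place of 6 (3), 3 nutrient members in place of 4 (7) and 4 phloem sap members in place of 1 (8). limma called none of the 19 defence gene regulators and none of the 5 machinery members, over all sequences or over the list alone. Each of these lists had 1 member with an unadjusted p under 0.05, and edgeR called 0, or 1 with TMM. limma with TMM called 1 machinery member lower and no defence gene regulator. miR168a was 36660 ± 20453 against 28534 ± 24773 TP5M. The miR167e call was lost with TMM and when any library other than the new leaf at flower bud differentiation was left out, and that of miR172a with young leaf only (germination and trefoil). Single libraries also ended the calls of gso-miR3522a (flower bud or the first florescence), M1574-3p (bud before flowering or 5 days), M5497-3p (other-date florescence, 5 days or old leaf at bud differentiation) and miR169n (any flower other than the first florescence, either trefoil leaf or old leaf at bud differentiation).

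Pod against flower compares successive organs. The legume family miR1512 rose most. miR1512c went from 277 ± 557 TP5M in flower (SD, n = 5) to 7003 ± 2793 in pod (n = 3), a log2 difference of 7.05 ± 1.10 (adjusted p = 0.000782; chromosome 2, 8609646 to 8609749, minus strand). Both arms of another miR1512-related hairpin rose with it, M0766-3p from 16.3 ± 13.1 to 626 ± 492 (log2 4.70, adjusted p = 0.000138) and M0766-5p from 15.9 ± 11.5 to 325 ± 196 (log2 3.96), and miR1512b was also called (1778 against 119). Among sequences high in flower, miR169v-3p fell to 8.07 ± 2.78 (log2 −5.91, adjusted p = 0.000881), miR4392 to 0 in all 3 pods (at least 284-fold lower), and miR171m, which targets HAM genes of the meristem, from 3600 ± 1799 to 308 ± 156 (log2 −3.43, adjusted p = 0.00699).

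The other calls were the falls of M4039-5p of miR319 (log2 −3.17), M2450-5p of miR171 (log2 −2.85), M3495-3p (log2 −2.49), miR167k-5p (log2 −2.25) and M4022-5p (log2 −1.59). In all, 4 sequences were higher and 8 lower (6 and 5 with TMM). 81 had an unadjusted p under 0.05, and 110 did not overlap, where chance gives 3.57%. Of 12 auxin members 1 fell (3 adjusted over the list alone), with a median log2 of −1.10 and a camera call (adjusted p = 0.0175; adjusted p = 0.529 with an estimated correlation) and a fry call for a shift one way (adjusted p = 0.0231, but 0.102 with unnamed related sequences added). miR167a was 278 ± 12.1 in pod against 2001 ± 1138. Of 68 legume members 2 rose (3 adjusted over the list alone), of 133 ancient members 3 fell (4), and of the meristem and nutrient lists 1 member each fell (1 each). limma called no phase change member (1 lower adjusted over the list alone; 2 with an unadjusted p under 0.05), and none of the copper, defence, machinery and phloem sap lists under either adjustment, where 0, 0, 0 and 1 members had an unadjusted p under 0.05. edgeR, with or without TMM, called 0 in these 5 lists and in the legume and nutrient lists, and 2 ancient, 1 auxin and 1 meristem member. The count was 35 without the other-date florescence library, where miR1512c stood at 1272 TP5M, and 6 without the pod of week 3 or that of week 2, which also ended the call of miR171m. Of 11 named sequences M0766-3p alone was called under every alternative: edgeR called 4 sequences (5 with TMM), not miR1512c or miR169v-3p, and M2450-5p, M4039-5p, M3495-3p and M4022-5p lost their calls without either of those pods, the latter 3 also without single flower libraries.

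Seed against pod compares filling seeds with young pods. Several miR167 members rose. miR167e went from 3266 ± 5488 TP5M in pod to 26951 ± 7355 in seed (SD, n = 3 each; log2 5.85 ± 1.21, adjusted p = 0.00263; chromosome 20, 37901896 to 37902004, plus strand), M4031-5p from 6178 ± 10466 to 54810 ± 10189 (log2 6.31, adjusted p = 0.00183), miR167c from 77.1 ± 35.7 to 741 ± 373 and miR167a from 278 ± 12.1 to 1704 ± 71.0. Most called members of the meristem list fell, as did most called sequences. miR166h-5p went from 1011 ± 525 to 2.02 ± 1.78 (log2 −7.10 ± 0.97, adjusted p = 6.77e-05), miR319n from 190 ± 54.7 to 1.07 ± 0.15 (log2 −4.97), and miR396b-5p from 18291 ± 4762 to 2442 ± 708 (log2 −2.91, adjusted p = 0.0238). miR172a fell from 104 ± 25.7 to 4.09 ± 2.73 (log2 −3.60, adjusted p = 0.00253).

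Among 3p arms related to miR156, a family that represses SPL genes, M0930-3p was 97.9 ± 27.2 in seed and 0 in every pod (at least 27.5-fold, log2 4.33, adjusted p = 2.17e-09) and M5008-3p was 267 ± 208 against 0.56 ± 0.98 (log2 5.19). Other rises were those of M0775-3p (305 ± 227 against 0.58 ± 0.50) and M0775-5p (at least 45.0-fold), both arms of 1 hairpin, gso-miR3522a (4036 ± 834 against 224 ± 43.5), M4031-3p (log2 3.65), miR397b-3p, from a family that targets laccases (78.5 ± 25.2 against 4.70 ± 4.83), and M7631-3p (log2 3.17). Falls included miR1512b (33.2 ± 12.6 against 1778 ± 886, log2 −5.46), M0766-5p (log2 −5.22), M3784-5p of miR166 (log2 −5.22), M1130-3p of miR164 (log2 −4.43), M4242-3p of miR530 (141 ± 91.4 against 2300 ± 798), M2642-3p (log2 −4.06), and M0196-3p of miR390 (log2 −4.01). M2634-5p was also called lower, but it was listed above 0 in 5 libraries alone, at 843.65 and 68.92 TP5M in 2 leaf libraries and at 87.07, 81.58 and 71.73 in the pods. In all, 24 sequences were higher and 73 lower (45 and 45 with TMM). 172 had an unadjusted p under 0.05, and 298 did not overlap, where chance gives 10%.

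Of 45 meristem members 1 rose and 8 fell (1 and 8 adjusted over the list alone; 3 and 7 with TMM), and of 12 auxin members 4 rose and 1 fell (4 and 3). Of all 595 sequences 24 rose and 73 fell. Neither camera nor fry for a shift one way called the meristem list in this contrast (adjusted p = 0.178 and 0.0554), but mixed fry did (adjusted p = 4.25e-06). Of 19 defence gene regulators 3 fell (3; 1 with TMM), among them miR1507a (6539 ± 1815 against 19581 ± 4748, log2 −1.59), whose call was lost with TMM, as were those of miR396b-5p, miR408a-3p and M2634-5p. Of 13 copper members miR397b-3p rose and miR408a-3p fell (1 and 1; 1 and 0 with TMM), the latter from 204 ± 39.5 to 10.7 ± 12.6 (log2 −4.00). Of 16 phase change members 2 fell, both miR172 (2), and of 133 ancient members 6 rose and 14 fell (5 and 14; 10 and 10 with TMM). Of 68 legume members 2 rose and 7 fell (2 and 7; 6 and 5 with TMM), of 40 nutrient members 3 fell (1; 1 and 1 with TMM) and of 26 phloem sap members 2 fell (2; 1 and 1 with TMM). edgeR called 2 nutrient members (1 with TMM) and 1 phloem sap member (1), and 3 defence gene regulators (1). limma, edgeR and edgeR with TMM called 0 of the 5 machinery members (0 adjusted over the list alone), and 0 had an unadjusted p under 0.05. The count was 58 without the seed of week 10, 64 without the pod of week 2 and 17 with the term for 6 libraries, all 3 pods among them. Calls of gso-miR3522a and M4242-3p were lost without the week 10 seed or the week 2 pod, of miR167c without the week 10 seed, and of miR167a, miR397b-3p, miR396b-5p, miR408a-3p, M1130-3p, M0196-3p and M2634-5p without any of several libraries. edgeR did not call miR167e and M4031-5p, which in pod were high at week 1 (9603 and 18263 TP5M) and at 70.7 and 88.1 at week 3.

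Seed against leaf compares a storage organ with leaf. Most called miR172 members were lower in seed. miR172a was 4.09 ± 2.73 TP5M (SD, n = 3) against 635 ± 442 in leaf (n = 6; log2 −5.80 ± 0.64, adjusted p = 5.07e-06) and M4097-5p 36.3 ± 9.25 against 2996 ± 2831 (log2 −5.70), whereas miR172c was higher on average (62.5 against 4.31). In the seed of 10 weeks, miR172c was only at that library's 3 read value of 3.35 TP5M. miR1512c was 949 ± 495 in seed against 1.03 ± 2.52 in leaf (log2 7.20 ± 1.06, adjusted p = 0.000115). miR167e was 23.7-fold higher (log2 4.57, adjusted p = 0.00484) and M4031-5p 20.6-fold (log2 4.39). miR408a-3p, which targets copper proteins, was 10.7 ± 12.6 against 701 ± 1189 (log2 −4.44, adjusted p = 0.0032).

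Further rises were those of M0930-3p (0 in every leaf, at least 27.2-fold, adjusted p = 1.73e-10), M5008-3p (log2 4.76), M0775-5p (log2 4.76) and M0775-3p (log2 4.85), M5447-3p of miR394 (369 ± 235 against 15.9 ± 26.4), miR828a (312 ± 327 against 3.64 ± 2.52) and M7043-5p of miR482 (10203 ± 4251 against 1314 ± 1549). Falls were those of miR166h-5p (log2 −5.79), M3784-5p (27.1 ± 22.7 against 1892 ± 2736), miR169n (0.70 ± 0.62 against 436 ± 735), M3552-3p (log2 −4.74) and M6343-3p (log2 −4.62) of miR156, M0854-3p of miR4416 (log2 −4.64) and miR319n (log2 −4.33). miR1507a fell (log2 −1.41, adjusted p = 0.0032) and miR1509a, a legume family, rose (13835 ± 7942 against 5860 ± 1772, log2 1.14, adjusted p = 0.0318). In all, 40 sequences were higher and 57 lower (68 and 55 with TMM). 186 had an unadjusted p under 0.05, and 96 did not overlap, where chance gives 2.38%.

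Of 16 phase change members 2 rose and 5 fell (2 and 6 adjusted over the list alone; fry for a shift one way, adjusted p = 0.0231, but 0.216 with unnamed related sequences added) and of 45 meristem members 1 rose and 8 fell (1 and 8). Neither camera nor fry for a shift one way called the meristem list in this contrast (adjusted p = 0.101 and 0.0569), but mixed fry did (adjusted p = 1.88e-06). Of 133 ancient members 7 rose and 20 fell (7 and 21; 11 and 19 with TMM), of 68 legume members 4 rose and 3 fell (4 and 3; 7 and 4 with TMM) and of 40 nutrient members 1 rose and 4 fell (0 and 3; 4 and 5 with TMM). Of 12 auxin members 1 rose and 2 fell (1 and 2; 2 and 1 with TMM), of 13 copper members 1 fell (1), of 19 defence gene regulators 3 fell (3), of 5 machinery members miR403a fell (1; none with TMM) and of 26 phloem sap members 2 fell (2; 2 and 2 with TMM). These counts depend on the method: edgeR called 44 ancient (37 with TMM), 16 legume (16), 13 nutrient (10), 13 meristem (10), 10 phloem sap (5), 5 copper (2), 4 auxin (5) and no machinery members (0). Over all 4 contrasts, none of the 3 camera calls held with an estimated correlation, and of 40 list results camera went against the sign of the median in 14, fry in 3 and the mean in 2. Mixed fry, which gives no direction, called 25 of the 40. The count was 56 without the seed of week 8, 62 without that of week 6, 34 with leaf and seed libraries alone and 157 with later leaf alone. Any seed library left out ended the call of M0854-3p, and either trefoil leaf or the seed of week 10 or 8 that of miR1509a.

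**Figure D2:**
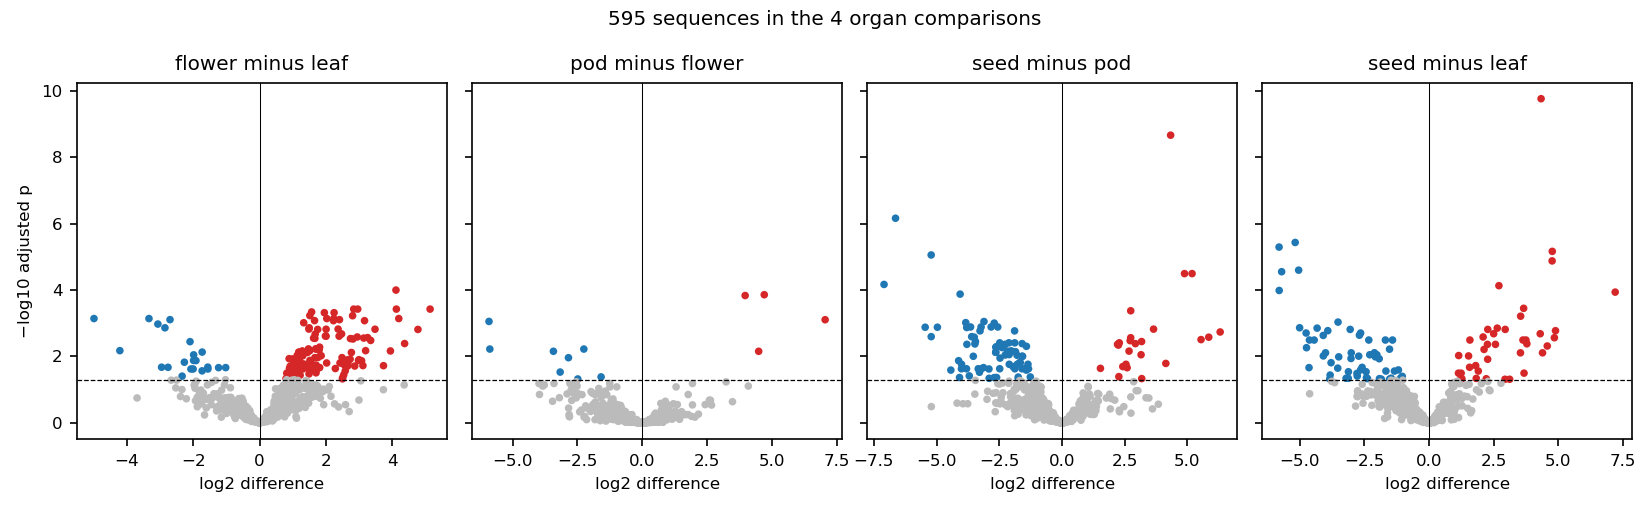
Log2 difference (horizontal axis) and −log10 of the adjusted p from limma (vertical axis) of 595 sequences in the 4 organ comparisons; red points are higher, blue lower, and the dashed line is 0.05. Flower minus leaf had 126 higher and 22 lower, and seed minus pod 24 higher and 73 lower.

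Neither the length classes nor the number of sequences detected passed an adjusted test at the reported settings. Sequences of 22 nt, the length that can trigger secondary siRNAs, took 23.0% ± 3.54 of the summed signal in seed, 14.3% ± 3.99 in leaf, 18.7% ± 1.91 in flower and 17.6% ± 2.34 in pod (SD, n = 3, 6, 5 and 3). Each seed library lay above every leaf library (exact permutation p = 0.0238, adjusted p = 0.0952), and with a mean of at least 50 TP5M the adjusted exact permutation p was 0.0476. Sequences of 24 nt took 0.204% ± 0.086 in seed and 0.069% ± 0.045 in leaf, with the same p and adjusted p. Sequences at 5 TP5M or more numbered 581 ± 42.9 in flower, 481 ± 84.1 in leaf, 573 ± 15.0 in pod and 443 ± 38.3 in seed. Adjusted exact p-values were 0.2 for flower against leaf, 0.857 for pod against flower, 0.2 for seed against pod and 0.635 for seed against leaf. With 3 libraries against 3, an exact p cannot go below 0.1.

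**Figure D3:**
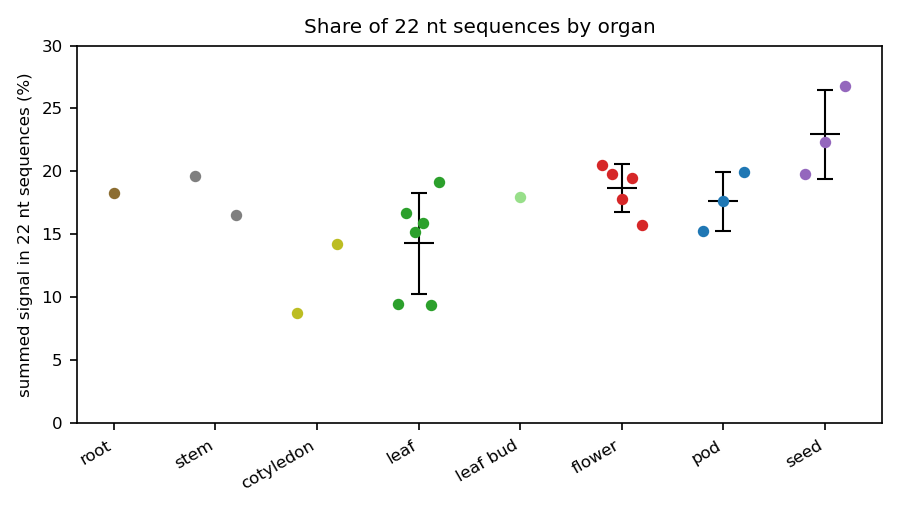
Share of the summed signal in 22 nt sequences (vertical axis, %) in each library by organ (horizontal axis); bars are mean and SD where an organ has 3 or more libraries. Seed averaged 23.0% and leaf 14.3%.

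Old and new leaves were compared at 2 stages, with 1 library on each side and so no test. The miR398 and miR396 families were higher in old leaf. miR398c-5p was 723 TP5M in old and 27.6 in new trefoil leaf, and 310 and 10.1 at flower bud differentiation. miR396a-5p was 11178 and 625 TP5M, then 11848 and 498. miR396i-3p, miR5761a, miR5371-5p, miR408a-3p and gso-miR3522a were also at least 4-fold higher in old leaf at both stages. Of 301 sequences, 75 were at least 2-fold higher in old leaf at both stages, 21 were lower at both, among them miR319n and miR169v-3p, and 14 went opposite ways (56, 40 and 16 with the median log2 ratio of each pair set to 0). In the trefoil pair 61 of 216 sequences were 4-fold higher or more and 19 lower (37.0%), and at flower bud differentiation 61 and 18 of 263 (30.0%). With the median log2 ratio of a pair set to 0, these splits were 43 and 29 at trefoil and 41 and 37 at flower bud differentiation. As a yardstick for such shares, the florescence libraries of 2 dates differed by 4-fold or more in 64 of 247 sequences (25.9%), 5 higher and 59 lower on the other date, or 18 and 18 (14.6%) with the median set to 0. This yardstick may be too high, because the other-date library stands apart from the other flower libraries, as described below. Flowers at 5 days after flowering and at florescence differed in 2.4%.

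At the trefoil stage, rises in old leaf included M5463-3p, related to miR3522 (11806 against 248 TP5M, 47.6-fold, 95% counting interval 41.7 to 54.5), and M0560-5p of miR166 (611 against 3.31, 184-fold, 62.8 to 897), and falls M3392-3p (33.7 against 410) and miR319n (10.8 against 106). At flower bud differentiation M3339-3p of miR393, a family that targets auxin receptors, was 293-fold higher (5671 against 19.4), M6343-3p 309-fold (1912 against 6.20), M5469-3p 63.5-fold and miR396i-3p 39.6-fold (35613 against 898), and M1130-3p of miR164 was 15.5-fold lower (79.4 against 1232). Senescent leaf lost miR169a (6.18 against 1137 in old leaf, 184-fold), M3552-3p of miR156 (1.03 against 753, 731-fold, 131 to 28940), M0196-3p of miR390 (5.15 against 794) and M1574-3p of miR394 (2.06 against 544, 264-fold, 72.8 to 2188). It gained miR393h (471 against 0, at least 160-fold), M7042-5p of miR156 (408 against 0.98, 416-fold, 74.2 to 16460) and miR156r (240 against 0.98, 245-fold, 43.5 to 9701), with 31 of 258 sequences higher and 82 lower (43.8%), or 49 and 59 with the median set to 0. Old trefoil leaf, however, held 680 TP5M of miR393h, more than senescent leaf, so its rise holds only against old leaf at flower bud differentiation. The miR156 family as a whole, summed with related sequences, was lower in senescent leaf (3148 against 11209 TP5M).

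Stem at trefoil against germination had 21 of 231 sequences higher and 40 lower (26.4%), or 28 and 23 (22.1%) with the median set to 0. miR2119 rose 24.9-fold (420 against 16.9 TP5M), and M7042-3p and M7042-5p fell 192-fold (12.7 against 2444) and 81.7-fold. Old cotyledon gained miR5761a (15952 against 40.8, 391-fold; chromosome 10, 50654873 to 50655068, minus strand), M0854-3p of miR4416 (7443 against 74.9, 99.4-fold) and miR5786-5p (346 against 0.74, 467-fold, 83.1 to 18470) and lost miR164a (177 against 2953, 16.7-fold), with 49 of 227 higher and 22 lower (31.3%). Flower bud against leaf bud had 24 of 240 higher and 8 lower (13.3%): M3339-5p and M3339-3p of miR393 were 36.9-fold and 39.4-fold higher in the flower bud, where the 2 florescence libraries differed 18.1-fold in M3339-3p (49.5 and 893 TP5M), and miR172b-5p was 12.7-fold lower (14.2 against 179). Root against stem had 5 of 204 higher and 128 lower (65.2%), with a median log2 ratio of −2.31. With that median set to 0 the count was 42 of 204, 20 higher and 22 lower. Higher in root were M2849-5p (532 against 0.85, 626-fold, 112 to 24890), miR159b-3p (333 against 24.5, 13.6-fold) and miR167c (7.08-fold), and M7042-3p and M6352-3p were among those lower than in stem.

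Flowers at 5 days after flowering and at florescence differed in 6 of 246 sequences (2.4%), and 5 of the 6 were among sequences at 0 or at high values. Pods at 3 weeks against 1 week differed in 25 of 218 (11.5%; 13 higher, 12 lower), or in 14 of 200 (7.0%) without sequences at 0 or at high values. miR396i-3p was 12.2-fold higher (15405 against 1260 TP5M), M4031-5p 207-fold lower (88.1 against 18263) and miR167e 136-fold lower (70.7 against 9603). Seeds at 10 against 6 weeks differed in 47 of 176 (26.7%; 20 higher, 27 lower). M7042-3p was 916 against 0.90 (1018-fold, 182 to 40280), M7042-5p 264-fold higher and miR395a, which targets sulfate assimilation genes, 37.3-fold higher (1007 against 27.0), while miR828a was 31.4-fold lower (21.2 against 666) and miR172c 33.0-fold lower (3.35 against 111, 11.1 to 162).

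Of the 96 pair results that the naming rule gave, 52 were sequences listed at 0 in some libraries and high in the others, or found only among a set of 6 libraries. No change is read from these 52. miR156a, for example, was listed at 8442.51 TP5M in old trefoil leaf, at 0 in new trefoil leaf, at 6270.69 in germination stem and at 0 in trefoil stem and root, and miR319d at 17272.82 and 0 in trefoil and germination stem. Others named by the rule were miR169e, miR1508c, M0560-3p, M0530-3p, M2135-3p, M2449-3p, M7060-5p, M0899-5p, M0223-3p, M0734-3p, miR1510b-3p, miR166m, miR319f, miR319h, M2634-5p, M0366-3p, M2492-3p, miR396a-3p and miR408d. The examples above hold none of them, a choice made after the values were seen.

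**Figure D4:**
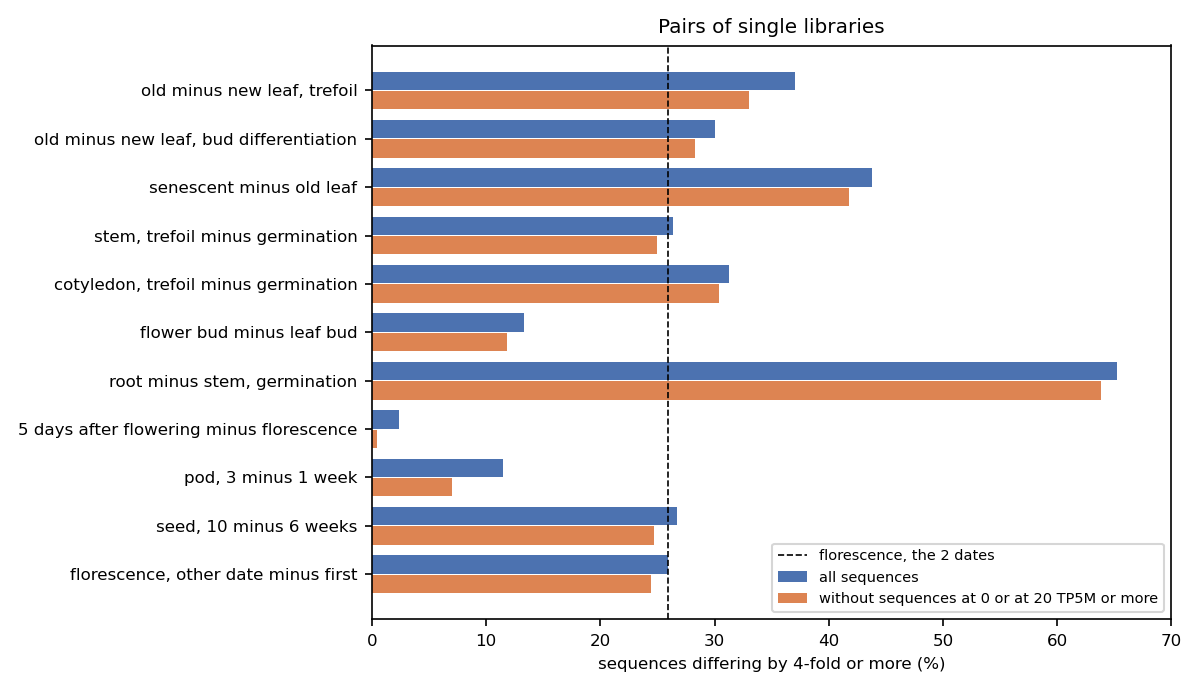
Share of sequences (horizontal axis, %) that differed by 4-fold or more in each pair of single libraries (vertical axis), over all sequences (blue) and without those at 0 in some libraries and at 20 TP5M or more in all others (orange). The dashed line is the pair of florescence libraries at 25.9%, and root against stem reached 65.2%. The other-date library of that florescence pair stands apart from the other flower libraries, so the line may be too high.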

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

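Chosen only after the results were seen were the tests of library depth, organ or stage differences, reads listed under other entries, other sets of 6 libraries, exchanged labels, and pod tissue with sequences left out. The tests of calls for a batch term and of pod tissue over all sequences were written down before their results, and the median of that term was looked at afterwards.

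In the flower and leaf groups, 152 sets of values were checked for 1 library lying far from the others of its organ, and 20 had one. Chance gives about 1 in 20 if values are normally distributed, which was not checked. Where all other libraries were at 0, as for miR1512c in senescent leaf, any value above 0 passes. The 20 of 152 can therefore not be judged against that rate. Of the 20, 10 were in the florescence library of the other date and 5 in senescent leaf, and values of 1 library are not independent of each other.

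The florescence library of the other date held 505 sequences at 5 TP5M or more (593 to 611 in the other 4 flower libraries) and a 24 nt share of 0.187% (0.074% to 0.105%). It was lowest in miR396b-5p, at 3055.92 TP5M (others 11600.47 to 16207.86), M4051-3p of miR319 at 557.53 (5628.41 to 9372.07), miR169v-3p at 122.39 (1084.79 to 1502.96), miR164a-3p at 48.21 (255.83 to 313.12) and M1130-3p of miR164 at 367.16 (733.39 to 852.01). It was also lowest in miR167c at 67.99 (237.74 to 339.89), miR172a at 66.76 (121.83 to 149.98) and miR159a-3p at 126478.14 (158785.44 to 166458.05). The table's sequences together took 6.78% of this library's tags (10.4% to 11.9% in the others). Its median log2 ratio to the first florescence was −1.086, so levels lower by about that much may follow this general shift. As a share of the summed signal, miR159a-3p was highest there, at 37.3% (28.1% to 31.5%).

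For this library, total depth is argued against by its total of 4.04 against 4.1, in units of 1e6 tags, for the first florescence. Its reads of the table's sequences were fewer, 274346 against 474503, and this was not tested as a cause. Pod tissue mixed in as the whole cause is argued against as well, on the TP5M scale. The lower signal of this library may widen the gap between the implied shares, and shares with its level adjusted were not computed. The 11 sequences higher in the 1 week pod implied a median pod share of 0% (quartiles 0 to 8.9) and the 59 lower ones 96.1% (lower quartile 85.1), and with the sequences listed at 0 or at high values and those of 6 libraries left out the medians were 17.5% and 96.1% (5 and 52 sequences, quartiles 0.3 to 33.2 and 85.8 to 100.1). An exchange with the 1 week pod is argued against by that pod's lowest correlation of 0.886 with the other pods and highest of 0.85 with the other flower libraries, although the other-date library itself correlated at 0.906 with the 1 week pod, 0.881 and 0.869 with the pods of weeks 3 and 2, and 0.863 to 0.904 with the other flower libraries. A single wrong label, the sampling date and a different flower stage stay open and were not tested.

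Some sequences were listed at exactly 0 in some libraries and at 20 TP5M or more in all others, 24 in all, among them miR156a, at 0 in new trefoil leaf (865.81 to 8442.51 in the other 5 leaf libraries). Organ differences are argued against, because 23 of the 24 had an organ with both kinds of value, and so is depth: for the 13 with a partner sequence, the partner predicted a level above what 3 reads were worth in 149 of 157 values of 0, and for the others 127 of 176 values of 0 stood in libraries with a larger total than the shallowest one listing the sequence. As a hypothesis, their reads may be listed under other entries, or not listed, in single libraries: the partner predicted 20 TP5M or more in 140 of the 157. With lower limits of 5, 10 and 50 TP5M the numbers were 190 of 238, 177 of 204 and 97 of 103. The ratio to the partner came only from libraries that list the sequence, all at the limit or above. For miR1511, with 22 of the 157 values, it came from 1 library. High predictions are thus partly built in and cannot decide the hypothesis, and the depth comparison with partners uses the same ratio. Which of these options holds stays open, and no biological explanation was tested beyond organ.

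A set of 6 libraries held old trefoil leaf, old and new leaf at flower bud differentiation and the 3 pods. In 1 or more of them, 16 sequences were listed that stood at 0 in the other 17 libraries. Only 3 of the 16 were above 0 in all 6, and miR1511 and M6029-5p were each above 0 in 1 alone. Depth is argued against, because 14 of the 17 other libraries had a larger total than the shallowest of the 6. A batch that moves other sequences too stays open: a term for these libraries called 1 sequence, and another of the 10 splits of the leaf libraries 90, but the expectation written beforehand rested on calls alone, and the median log2 of the term over all other tested sequences was 0.469 in size, against at most 0.453 in the other splits, which are too few for a share under 0.05. Chance and organ or stage stay open: the highest count in other sets of 6 was 6, and the mean in the 5 other leaf and flower bud differentiation libraries was 0, but the set and its sequences were picked by these same values. A difference in which sequences were listed for these libraries also stays open and was not tested.

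Senescent leaf had 5.15 TP5M of M4051-3p (302.07 to 947.25 in the other 5 leaf libraries), 6.18 of miR169a (1136.67 to 4691.78), 15.44 of miR169s (445.79 to 1286.55), 25.74 of M5008-3p (0 to 1.96) and 6.18 of miR1512c (0 in each). Old leaf at flower bud differentiation had 9.81 TP5M of M0766-5p (0 to 1.2 in the other leaf libraries). New leaf at germination had 35.76 TP5M of M0775-3p (0 to 3.61). The flower bud had 27.36 TP5M of M0775-5p (0 to 2.85 in the other flower libraries) and 2.83 of M6343-3p (0 in each), the latter under the largest 3 read value. In old against new leaf, 14 sequences differed by 2-fold or more in opposite directions at trefoil and at flower bud differentiation, a difference that was not tested. Of these, 8 were at 0 in at least 1 of the 4 libraries.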

How the results depend on the processing

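Tests added only after the results were seen are the edgeR test, young or later leaf only, the term for 6 libraries, fits without sequences listed at 0 or at high values, widened families and thinned reads. Over 165 reported results, 2268 of 2457 values from alternatives other than leaving out 1 library kept direction and side of the threshold, 135 lost the call or, for a count, fell by over 1.5 times, 50 gained it or rose by as much, and 4 reversed; for 1 library left out the numbers were 1294, 94, 22 and 0 of 1410. Under every alternative 10 of 20 named sequences stayed called in flower against leaf, 1 of 11 in pod against flower, 8 of 20 in seed against pod and 14 of 20 in seed against leaf. The cause was not tested for the changes that follow, except where fewer or more sequences or libraries entered a fit. Flower against leaf (148 called) gave 56 with a mean of at least 50 TP5M, 223 with each entry counted separately, 94 with those organs alone, 77 with later leaf only and 95 with edgeR. Pod against flower (12) gave 23 without a filter, 36 with those organs alone, 4 with edgeR and 5 with edgeR and TMM. Seed against pod (97) gave 205, 44, 153 and 194 without a filter, with a mean of at least 50, with separate entries and with those organs alone, and 17 with the term for 6 libraries, which is estimated from leaf only and costs precision. That term also moved the median log2 difference of seed minus pod from −0.639 to −0.12. Seed against leaf (97) gave 233 without a filter, 153 with separate entries, 34 with those organs alone, 157 with later leaf only, 62 with the term, 160 with edgeR and 149 with edgeR and TMM. The 4 organ test (235) gave 401 without a filter, 105 with a mean of at least 50 and 353 with separate entries. Leaving out 1 library gave 108 to 212, 6 to 35, 58 to 84, 56 to 109 and 194 to 284 calls in that order. The 35 came without the other-date florescence, 6 without the pod of week 3 or 2, 58 without the seed of week 10, 64 without the pod of week 2, and 56 and 62 without the seeds of weeks 8 and 6. Without the sequences listed at 0 or at high values the counts were 157, 12, 95, 95 and 240. The sequences that reversed were not called in the reported fits. miR159a-3p was lower in flower than leaf with TMM (log2 −0.609, limma adjusted p = 0.0148) and with edgeR and TMM (−0.624, adjusted p = 0.0315), and higher in seed than pod with TMM (0.727, limma adjusted p = 0.0316), where its adjusted p ran from 0.0148 to 0.984 and from 0.0316 to 0.955 over the alternatives. M4779-5p was higher in seed than in young leaf only (log2 2.032, limma adjusted p = 0.00857; range 0.00226 to 0.964 over the alternatives, the lowest with later leaf only, where it was lower in seed). Thinned reads and other detection limits left the tests of sequences detected on the same side of the threshold, as did other detection limits and unnamed families for family breadth. The 22 nt share of seed minus leaf became 8.697 points (adjusted exact p = 0.0476) with a mean of at least 50 TP5M, where the exact p itself was 0.0119 in place of 0.0238 and 4 comparisons were adjusted. In pairs of libraries at 250 TP5M or more, fewer sequences entered, and the numbers 4-fold apart were 50 for trefoil leaf, 40 for leaf at flower bud differentiation, 65 for senescent leaf, 28 for stem, 41 for cotyledon, 14 for flower bud, 77 for root, 16 for pod, 26 for seed and 36 for the 2 florescence dates. A pseudocount of 25 gave 38 for stem, 18 for flower bud, 30 for seed and 39 for the florescence dates, and setting the median ratio to 0 gave 42 for root and 36 for the florescence dates. Without sequences at 0 or at high values, 5 days against florescence gave 1 (1 by the wider rule) and pod 14 (13 by the wider rule). Of sequences higher or lower in old leaf at both stages and of those opposite, 4-fold left 32, 6 and 9, and setting the median to 0 gave 56, 40 and 16. With families widened by related sequences, camera called 9 of 40 list results in place of 3, none with an estimated correlation, and fry for a shift one way called 0 in place of 2 (lowest adjusted p = 0.102). Depth limits sequences near 3 reads, worth 2.22 to 4.14 TP5M. Not run were DESeq2 and the raw count form of edgeR.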

Other observations

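Chosen only after the results were seen were the tests of other splits of the libraries and the test of miR172 in leaf.

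Old cotyledon carried the highest levels of miR398c and gso-miR3522a, and both cotyledons were high in them. miR398c, which targets copper superoxide dismutases, was 55156 TP5M in old and 16893 in germination cotyledon (chromosome 8, 14299247 to 14299356, minus strand). It was 17319 in old trefoil leaf and at most 2097 in leaf libraries other than that and senescent leaf (7858). gso-miR3522a was 110428 and 48963 in the 2 cotyledons and 36538 in old trefoil leaf. miR408a-3p, of another copper family, was 7783 in old and 6055 in germination cotyledon and 3116 in old trefoil leaf. miR5761a was highest in senescent leaf (58752 TP5M) and old cotyledon (15952), whereas new leaf at germination was listed at 0.

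Stem held the highest level of miR319a, from a family that targets TCP genes of leaf growth. It was 39247 TP5M in trefoil and 39125 in germination stem and 20020 in florescence, the next highest library, with 69.0 in senescent leaf (chromosome 5, 40832084 to 40832290, plus strand). miR167e was low in stem (128 and 16.4 TP5M). Cotyledon and stem have 2 libraries each, and these levels were described and not tested.

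Early leaf (germination and trefoil) and later leaf (flower bud differentiation and senescence) held 3 libraries each. A hypothesis, formed from these data and left open by them, is that miR172 members may rise together from early to later leaf, as the phase change pathway is known to do in other plants. Of the 5 named miR172 members, 5 had a higher mean in later leaf, but so had 421 of all 595 sequences (70.8%), and 4 of the 5 rose by more than the median sequence (log2 0.477). Among the 5 were miR172a (274 TP5M early and 996 late), miR172h-5p (23.4 and 233) and miR172k (15.0 and 70.9). miR172b-5p (336 and 379) and miR172k overlapped between the groups, miR172k with a lowest late value of 22.7 and a highest early value of 25.4. miR172c (1.90 and 6.72) lay near the 3 read value. The values of miR156 members did not move one way: miR156c was 1737 early and 776 late and miR156i-3p 113 and 10.1, but miR156p was 6.12 and 44.9. Later leaf includes senescent leaf, and stage and leaf position differ between the libraries, so neither age nor a rise particular to miR172 can be read from them.

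Random regroupings of the same libraries were counted against the calls. For flower against leaf 2 of 100 drawn splits, the real one included, gave as many as the real 148, a share under 0.05. The highest other split gave 211, the one that put new leaf at flower bud differentiation with the flowers. For pod against flower 2 of 56 gave as many as the real 12, with a highest other of 12 (flower bud, bud before flowering and florescence against the rest). For seed against leaf 3 of 84 gave as many as 97, and the highest other was 149 (old trefoil, old flower bud differentiation and senescent leaf against the rest), a split that follows leaf age. For the 4 organs 1 of 100 gave as many as 235, with a highest other of 56. These shares were under 0.05, but they were not adjusted over the comparisons. In flower against leaf, pod against flower and seed against leaf another split equalled or passed the real count, so chance is not excluded there. For the 4 organs no other drawn regrouping reached the real count. The splits of seed and pod are too few (1 of 10, the real one) for a share under 0.05, with a real value of 97 and a highest other of 0.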
